A study of Homo sapiens with 6 samples.

How the data were processed

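RNA from AGS cells was extracted with TRI Reagent and made into libraries with a SMARTER mRNA-Seq kit, per the labels' protocols. The series holds 6 libraries, 3 of WT cells and 3 of cells given an siRNA against SRSF2, and groups and replicate numbers were taken from the sample labels. Sample titles and table columns of the siRNA group read siSRSF with a replicate number and do not name the gene, while the genotype label and the series title name SRSF2 as the target. The authors deposited raw read counts per gene in 1 table of 56303 gene entries, without normalization. Per the submitters' processing notes, HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used, and the genome build is named as mm10, a mouse build. The deposited table itself holds human gene names and human exon positions. Of 35985 gene names found once in GENCODE release 29 (GRCh38), 98.4% had the same position in the table, so positions are given here as GRCh38. Strand setting, read filters and the treatment of reads that match several genes or places are not given in the sources used here.

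Counts had been grouped by gene name, so that 139 names join genes of more than 1 chromosome, which held 0.161% of counts. In 28 entries a gene name had been turned into a date by spreadsheet software, and all 28 were restored from their positions. Gene classes came from GENCODE by name or, for 19943 entries, by reciprocal overlap of at least 0.8, and 950 entries stayed without a class. Of 648 list entries, 639 were found as written and 9 by an older symbol. Some of the latter repeated a gene already listed under that symbol, and a gene was counted once per list.

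Total counts ranged from 47518943 to 50021152 in WT libraries and from 26610937 to 36651623 in siSRSF2 libraries. Changes of low-count genes are therefore less precise in siSRSF2 libraries. The reads carry no molecular identifiers, so floors based on 3 counts cover counting error only. Replicates were compared by chi-square over genes with at least 20 counts. Every pair within a group differed by more than sampling noise (3.83 to 8.75 per gene), so no library was treated as a repeat of another.

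Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low-count genes were removed with filterByExpr (minimum count 10), which kept 23689 genes and 99.9% of counts, and libraries were scaled by TMM. The quasi-likelihood F test with robust fitting compared siSRSF2 with WT, with group as the only term and Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 6.27%. CPM values (counts scaled to a library size of 1e+06) use TMM-scaled library sizes, and SEs were derived from the log2 fold change and its F statistic. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 28 lists.

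The 28 lists, the tests and the rule for named genes were fixed before the data were examined. The rule took SRSF2 first. It then took the 10 largest rises and 10 largest falls among protein-coding and long non-coding genes with at least 5 CPM in the higher group and no overlap between groups. For each list it added up to 4 members with the smallest p where the list passed or at least 25% of its tested members changed, and up to 2 otherwise. All tested SR protein genes were added. Some genes that the rule selects are not reported here. The lists covered SR proteins, hnRNP proteins, the core spliceosome, splicing kinases, nonsense-mediated decay factors and targets, G1/S and G2/M genes, p53 targets, apoptosis, homologous recombination, interferon, NF-kB, the unfolded protein response, heat shock, immediate-early and ERK feedback genes, Wnt targets, epithelial, mesenchymal and gastric genes, hypoxia and glycolysis, cholesterol synthesis, ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, leukocyte markers, and fibroblast and endothelial markers.

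The pipeline was tested on simulated counts drawn from the means and library sizes of this comparison, with planted changes among 23160 genes in the fit. Of the 46 to 50 genes planted at each fold, 24.5% were recovered at 1.2-fold, 66% at 1.5-fold, 68% at 2-fold and 97.8% at 4-fold. At 2-fold, 90.6% were recovered among genes of mean CPM of at least 1 and 27.8% below that level. False calls made up 5.34% of calls. Of 200 random lists, 8 had a camera p under 0.05 before adjustment and none passed after it. Each gene was drawn independently, so these lists could not show false calls that arise from correlation among members.

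Alternatives were DESeq2 1.42.0 with its own size factors, limma voom, median-of-ratios (RLE) factors in edgeR, scaling by library totals, no filter beyond a total above 0, a mean CPM of at least 1, mitochondrial genes left out, a non-robust fit, the replicate number as a block, each library left out in turn and a test against a change of 1.2-fold. Lists were also tested with an estimated correlation and with fry. With an estimated correlation, camera takes its degrees of freedom from the libraries, and with a preset one from the genes tested. Thinning of all libraries to the smallest total and offsets for GC content and length were added after the data had been seen. Only gene-level counts were used, so splicing itself was not analysed here.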

Results

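RNA levels were measured by RNA sequencing in AGS cells, an established human gastric adenocarcinoma line. Cells transfected with a small interfering RNA (siRNA) against SRSF2 (siSRSF2, 3 libraries) were compared with cells labelled wild-type (WT, 3 libraries). SRSF2 encodes a serine/arginine-rich (SR) protein that binds exonic sequences and promotes their inclusion during pre-mRNA splicing. The labels do not say whether the WT cells received a control siRNA, nor whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. Read counts per gene summed to 49849185, 47518943 and 50021152 in the WT libraries and to 26610937, 36651623 and 32647728 in the siSRSF2 libraries. Levels are given as CPM, the count scaled by library size, and a count of 3 corresponded to between 0.0630 and 0.110 CPM in a single library, counting error only. The first principal component held 75.2% of the variance and separated the groups.

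The comparison asked how the transcriptome of AGS cells differed when SRSF2 was silenced. SRSF2 itself (chromosome 17, 76734115 to 76737374, minus strand, GRCh38 positions, 2 merged exons) was lower in siSRSF2 cells, at 22.7 ± 1.83 CPM against 45.0 ± 1.19 CPM in WT (SD, n = 3 per group). The counts behind these levels were 2122, 2118 and 2093 in WT and 586, 840 and 861 in siSRSF2. The log2 fold change was -0.98 (SE 0.064, edgeR adjusted p = 4.39e-13), and all 3 siSRSF2 libraries lay below all 3 WT libraries. Among the 23689 genes tested, 1447 (6.11%) passed the test with a lower log2 fold change than SRSF2. SRSF2 exons share positions with MFSD11 on the opposite strand, whose log2 fold change was -0.41 (SE 0.062, edgeR adjusted p = 2.55e-06). The strand setting of the counting is not given in the sources used here, so reads in the shared part could have been assigned to either gene or to neither.

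Most other SR protein genes fell together with SRSF2. Of 12 tested, 11 were lower, none was higher, and SRSF11 did not pass the test (log2 fold change -0.03, SE 0.067, edgeR adjusted p = 0.725), its sign turning positive (0.10) when libraries were scaled by their totals alone. The SR list was lower as a group (median log2 fold change -0.69, camera adjusted p = 8.34e-05; adjusted p = 0.178 with an estimated correlation). SRSF6 fell from 320.1 ± 14.4 to 115.0 ± 8.33 CPM (log2 fold change -1.48), SRSF8 from 11.0 ± 0.541 to 4.82 ± 0.502 CPM (-1.20), SRSF3 from 307 ± 5.72 to 136 ± 14.4 CPM (-1.18) and SRSF7 from 172 ± 5.36 to 85.9 ± 0.705 CPM (2.01-fold). These 4 genes had lower log2 fold changes than the siRNA target, which ranked 5 among the 13 SR protein genes. The values of SRSF7 (-1.004, SE 0.046) and SRSF2 (-0.983, SE 0.064) differed by less than either SE, so their order is uncertain. TRA2B (-0.80), SRSF1 (-0.76), SRSF5 (-0.62), SRSF9 (-0.45), TRA2A (-0.40) and SRSF4 (-0.35) fell by less. SRSF10 fell by 0.17 on the log2 scale and no longer passed with scaling by library totals (log2 fold change -0.04, edgeR adjusted p = 0.396), nor when tested against a change of 1.2-fold (adjusted p = 0.97). SRSF2 lay 0.28 log2 units below the mean change of the other SR protein genes (difference -0.28, SE 0.066 between libraries), which was within the spread among those 12 genes (SD 0.44). The exact permutation test of that difference, two-sided, gave p = 0.1, the smallest that 3 against 3 libraries allow.

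**Figure D1:**
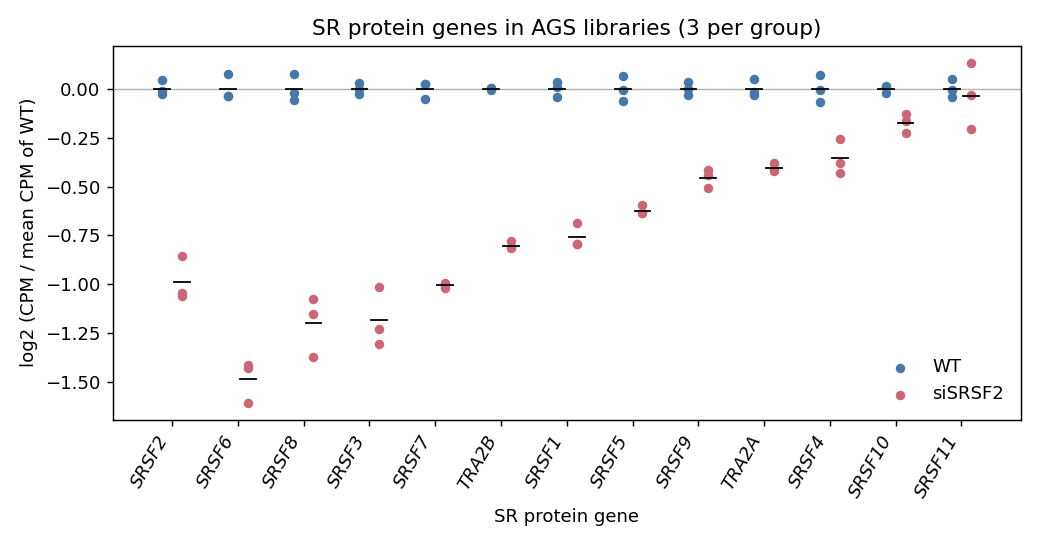
The y axis gives log2 of CPM over the mean CPM of WT for each SR protein gene on the x axis, with 1 point per library (3 WT, 3 siSRSF2) and horizontal bars at the group means. SRSF2 is placed first. SRSF6, SRSF8, SRSF3 and, by little, SRSF7 show larger mean falls than SRSF2, and the siSRSF2 points of SRSF11 overlap those of WT.

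The difference between the groups extended over much of the transcriptome. Of 23689 tested genes, 13991 (59.1%) passed an edgeR adjusted p of 0.05, 7129 higher and 6862 lower in siSRSF2. Changes over 2-fold were more often rises, in 3183 genes, than falls, in 1399 genes. The groups did not overlap in 15110 genes (63.8%), where chance gives 10%. With libraries scaled by their totals alone, the median log2 fold change shifted by 0.13 and the calls became 8560 higher and 5492 lower, 60.9% higher in place of 51.0%. Over 2-fold, 929 genes were then lower. With only genes of mean CPM of at least 1, the counts over 2-fold were 1991 higher and 881 lower.

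The largest changes were ranked among protein-coding and long non-coding genes with at least 5 CPM in the higher group and no overlap between groups. Among these, OTOGL, which encodes an otogelin-like protein of inner-ear extracellular matrix, rose most, from 0.136 ± 0.0784 to 14.5 ± 0.245 CPM (log2 fold change 6.72, SE 0.20, edgeR adjusted p = 6.28e-20). It lies on chromosome 12 at 80209453 to 80379090, and its WT level rests on counts of 3, 10 and 6. A locus on chromosome 15 held 3 of the 10 largest rises. These were the long non-coding RNA RP11-414J4.2 (74816223 to 74831795; log2 fold change 5.41), CPLX3, a complexin of synaptic vesicle release (74826547 to 74831802; 5.22), and LMAN1L, an intracellular lectin-like gene (74812716 to 74825758; 4.58). RP11-414J4.2 shares exon positions with both CPLX3 and LMAN1L on the same strand, so the 3 values are not separate measurements. Without WT replicate 1, the log2 fold change of CPLX3 was 6.60 and that of RP11-414J4.2 was 6.03. NFATC4, a calcineurin-dependent transcription factor, rose 37.1-fold (0.206 ± 0.0949 to 7.73 ± 0.832 CPM). GIPR, the receptor of the incretin GIP, rose 27.6-fold (0.301 ± 0.162 to 8.36 ± 0.942 CPM). TCP11L2 rose 24.9-fold from a higher level, 1.79 ± 0.421 to 44.6 ± 0.843 CPM. FAM83F (24.9-fold), the long intergenic RNA LINC00887 (20.6-fold) and MIR210HG (19.7-fold), the host transcript of a hypoxia-inducible microRNA, completed the 10 largest rises. TCP11L2 and FAM83F also share exon positions with another annotated gene (CKAP4 and RP3-496C20.1).

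ETV5, an ETS transcription factor induced by ERK signalling, fell most among the genes ranked in this way, from 5.64 ± 0.375 to 0.239 ± 0.0435 CPM (log2 fold change -4.54, SE 0.22, edgeR adjusted p = 1.62e-15). It lies on chromosome 3 at 186046308 to 186110318, and its siSRSF2 level rests on counts of 6, 8 and 10. THBS1, which encodes the matrix glycoprotein thrombospondin-1 (chromosome 15, 39581079 to 39599466), fell 13.4-fold from 434.9 ± 18.1 to 32.5 ± 1.18 CPM. CTD-2033D15.3, a transcript on the opposite strand within THBS1, fell 16.3-fold, and its reads cannot be told from those of THBS1 without strand information. The same limit holds for the adhesion protein gene AMIGO2 (13.6-fold lower, 59.8 ± 3.42 to 4.39 ± 0.230 CPM) and PCED1B (9.05-fold lower), which overlap on opposite strands of chromosome 12. TGM2, encoding tissue transglutaminase, fell 10.8-fold. HSPA1A and HSPA1B, near-identical neighbouring genes for stress-inducible chaperones on chromosome 6, fell 8.07-fold and 6.98-fold, and how reads were divided between them is uncertain. The secreted Wnt inhibitor gene DKK1 fell 7.08-fold and TNFRSF12A, the receptor of the cytokine TWEAK, 6.53-fold. ETV5, TGM2 and TNFRSF12A also share exon positions with another annotated gene (DGKG, RPRD1B and CLDN6).

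**Figure D2:**
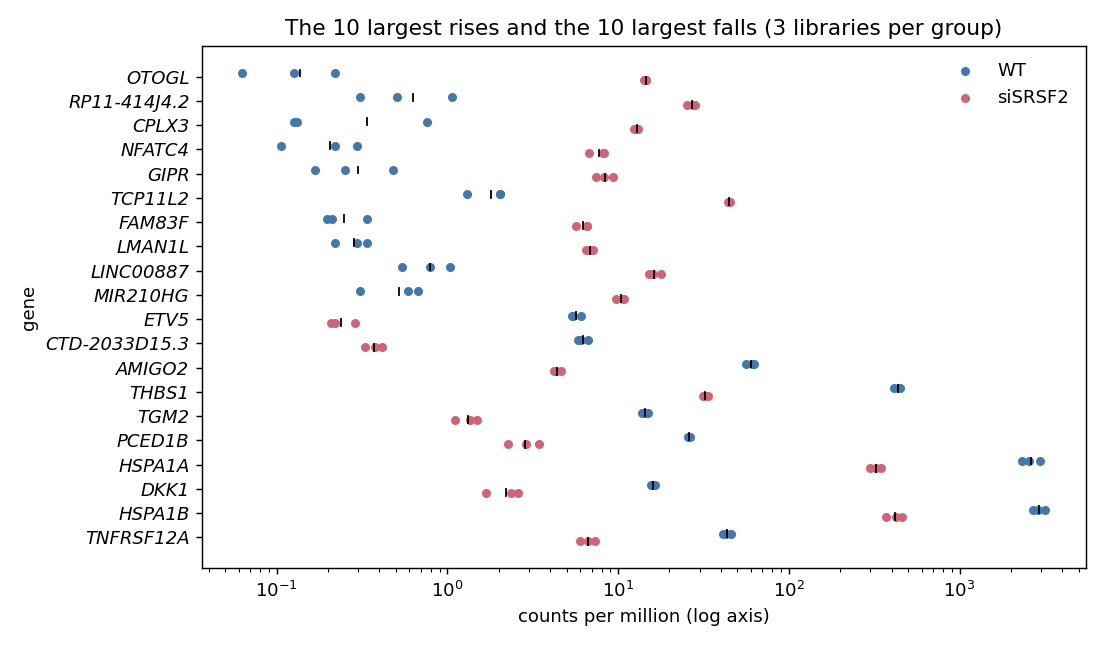
The x axis gives CPM on a log axis and the y axis the 10 genes with the largest rises followed by the 10 with the largest falls, with 1 point per library (3 WT, 3 siSRSF2) and vertical bars at the group means. Only protein-coding and long non-coding genes with at least 5 CPM in the higher group and no overlap between groups were ranked. In each gene the siSRSF2 points lie apart from the WT points, for example OTOGL near 14.5 CPM against 0.136 CPM.

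Genes of the splicing machinery beyond the SR proteins were mostly lower. Of 35 core spliceosome genes, 31 fell, none rose and 4 did not pass (median log2 fold change -0.63, camera adjusted p = 1.75e-08; adjusted p = 0.178 with an estimated correlation). PRPF4, of the U4/U6 particle, fell from 171 ± 2.77 to 72.9 ± 3.81 CPM (log2 fold change -1.23), and PRPF19 (-1.10), U2AF2 (-0.98), which recognises polypyrimidine tracts, and PRPF3 (-0.92) fell as well. Of 26 hnRNP genes, whose products package pre-mRNA and often counteract SR proteins, 21 fell and 2 rose (median -0.49, camera adjusted p = 5.33e-05; adjusted p = 0.293 with an estimated correlation). HNRNPAB fell from 701 ± 10.9 to 283 ± 13.5 CPM (-1.31) and SYNCRIP from 1014 ± 16.5 to 499 ± 1.56 CPM (-1.02), followed by HNRNPM (-0.83) and HNRNPU (-0.74). The kinases that phosphorylate splicing factors did not pass as a group, with 4 of 8 higher and 3 lower (camera adjusted p = 0.67). CLK1 rose 1.62-fold, CLK2 1.33-fold and CLK3 1.25-fold, and PRPF4B fell (-0.52). With offsets for GC content and length, CLK3 no longer passed (log2 fold change 0.07, edgeR adjusted p = 0.182), nor when tested against a change of 1.2-fold (adjusted p = 0.0683).

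Factors of nonsense-mediated decay, which degrades transcripts with premature stop codons, were lower in 12 of 15 cases and higher in 2 (median log2 fold change -0.48, camera adjusted p = 0.00372; adjusted p = 0.344 with an estimated correlation). The exon junction complex genes MAGOH (-1.28), RBM8A (-1.15) and EIF4A3 (-0.89) fell, as did SMG5 (-0.84). Transcripts known to be degraded by this pathway were also lower, 14 of 20, with 3 higher (median -0.30, camera adjusted p = 0.0105; adjusted p = 0.188 with an estimated correlation). TMEM33 (-1.19), UPF1 (-0.66) and the non-coding RNA GAS5 (-0.45) fell. SMG1, SMG5 and UPF1 encode decay factors and stand in both lists. The call on the second list ended when only genes of mean CPM of at least 1 were tested (camera adjusted p = 0.0537).

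All 14 tested heat shock genes fell (median log2 fold change -1.30, camera adjusted p = 2.04e-08; adjusted p = 0.178 with an estimated correlation). HSP90AA1, the inducible cytosolic chaperone of many kinases, dropped from 9462 ± 31.7 to 3250.0 ± 96.4 CPM. HSPA8 fell from 2915 ± 116 to 880.1 ± 12.5 CPM, DNAJA1 from 1480.0 ± 62.0 to 527 ± 14.1 CPM and HSPH1 from 565 ± 17.5 to 136 ± 4.46 CPM (log2 fold change -2.05). Genes of the unfolded protein and integrated stress responses went both ways, 5 higher and 13 lower of 26 (camera adjusted p = 0.173). Scaling by library totals gave 9 higher and 10 lower. In that list the endoplasmic reticulum chaperone HSPA5 (-1.40) and the amino acid synthesis genes PSAT1 (-1.63) and ASNS (-1.19) fell, whereas DDIT4, an inhibitor of mTORC1, rose from 223 ± 12.8 to 666 ± 28.0 CPM.

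Genes that report ERK pathway output were lower, 8 of 12, with none higher and 4 not past the test (median log2 fold change -1.64, camera adjusted p = 0.000283; adjusted p = 0.178 with an estimated correlation). Besides ETV5, the cell cycle gene CCND1 fell from 179 ± 1.92 to 37.5 ± 3.15 CPM (-2.25), the receptor gene EPHA2 from 37.8 ± 1.94 to 6.29 ± 0.749 CPM (-2.59) and the ERK phosphatase gene DUSP4 from 14.2 ± 1.65 to 2.69 ± 0.479 CPM (-2.42). Immediate-early genes did not pass as a group (4 higher, 9 lower of 18, camera adjusted p = 0.129). FOSL1 (-2.27), CYR61 (-1.88) and MYC (-0.62; 346 ± 5.69 to 226 ± 2.89 CPM) fell, and FOS rose 4.09-fold. Among Wnt target genes, 6 of 11 were higher and 3 lower (camera adjusted p = 0.63), with KREMEN1 (1.64) and AXIN2 (1.62) up and DKK1 (-2.82) and ZNRF3 (-1.25) down.

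Hypoxia and glycolysis genes were higher in siSRSF2 cells, 19 of 28, with 5 lower (median log2 fold change 0.61, camera adjusted p = 0.000289; adjusted p = 0.344 with an estimated correlation). ENO2 rose from 4.38 ± 0.202 to 46.0 ± 3.44 CPM (10.5-fold), and the oxygen sensor gene EGLN3 from 4.26 ± 0.637 to 39.0 ± 3.29 CPM (9.16-fold). PFKFB4 rose 4.72-fold and the mitophagy receptor gene BNIP3 3.42-fold. Cholesterol synthesis genes did not pass as a group (13 higher, 7 lower of 24, camera adjusted p = 0.142). INSIG1 (4.33-fold), FDFT1 (2.47-fold) and the master regulator SREBF2 (1.98-fold) rose, and NSDHL fell (-1.11). Cytosolic ribosomal protein genes did not pass as a group (7 higher, 17 lower of 50, camera adjusted p = 0.308). Their median log2 fold change of -0.08 became 0.05 with scaling by library totals, where 19 were higher and 6 lower. RPL3 rose 1.39-fold, and RPS13 (-0.58), RPL6 (-0.31) and RPS15 (-0.27) fell, of which RPL6 (edgeR adjusted p = 0.0813) and RPS15 (0.375) did not pass when tested against a change of 1.2-fold. Nuclear-encoded oxidative phosphorylation genes were 6 higher and 13 lower of 30 (camera adjusted p = 0.274). The median of this list, -0.12, became 0.01 with scaling by library totals, and the counts became 12 higher and 10 lower. SDHA rose 1.42-fold, and NDUFS3 (-0.55), SDHB (-0.53) and CYC1 (-0.44) fell.

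Mitochondrially encoded mRNAs were lower in 8 of 13 cases and none was higher (median log2 fold change -0.29, camera adjusted p = 0.0391; adjusted p = 0.623 with an estimated correlation). MT-ND5 (5971 ± 621 to 3388 ± 56.7 CPM), MT-ND3 (-0.81), MT-ND1 (-0.61) and MT-ND4L (-0.53) fell. All mitochondrially encoded genes together took 3.20% ± 0.180 of counts in WT and 2.91% ± 0.166 in siSRSF2 libraries (SD, n = 3 per group). This list lost its call with scaling by library totals (camera adjusted p = 0.0733), with genes of mean CPM of at least 1 (0.12), without siSRSF2 replicate 2 (0.0816) and without siSRSF2 replicate 3 (0.0728).

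Neither list of proliferation genes passed the list test. G2/M genes were 17 higher and 7 lower of 27 (camera adjusted p = 0.173), and CENPF (1287 ± 10.9 to 2323 ± 92.5 CPM), TOP2A (561 ± 6.08 to 1002 ± 49.98 CPM), HMMR (1.70-fold) and NUSAP1 (1.68-fold) rose. G1/S and DNA replication genes were 7 higher and 10 lower of 28 (camera adjusted p = 0.427). Their median log2 fold change of -0.06 became 0.07 with scaling by library totals, where 11 were higher and 8 lower. UHRF1 (-0.78), CDC6 (-0.47) and TYMS (-0.46) fell, and the licensing factor CDT1 rose (0.88). Targets of p53 split, 13 higher and 9 lower of 25 (camera adjusted p = 0.341), with BTG2 (1.84) and DDB2 (1.16) higher and AEN (-1.53) and TRIAP1 (-1.28) lower. Regulators of apoptosis were 12 higher and 8 lower of 28 (camera adjusted p = 0.482). The pro-apoptotic genes BMF (0.283 ± 0.0599 to 3.79 ± 0.381 CPM) and BCL2L11 (1.81-fold) rose, the inhibitor gene BIRC3 rose 3.47-fold and the anti-apoptotic MCL1 fell (-0.65). The median of this list was -0.0001 and its mean 0.38, and the median became 0.13 with scaling by library totals. Homologous recombination and Fanconi anaemia genes were 11 higher and 8 lower of 27 (camera adjusted p = 0.658), with FANCE (0.96) and RAD54L (0.64) higher and BRCA2 (-0.60) and RBBP8 (-0.50) lower.

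Interferon-stimulated genes were higher, 15 of 26, with 2 lower and 9 not past the test (median log2 fold change 0.75, camera adjusted p = 0.00499; adjusted p = 0.178 with an estimated correlation). IFIT1 rose from 1.13 ± 0.205 to 4.79 ± 0.291 CPM, IFI44L from 6.42 ± 0.478 to 20.4 ± 1.95 CPM, STAT2, a subunit of the interferon-activated transcription factor, from 6.91 ± 0.219 to 21.0 ± 1.63 CPM, and the surface protein gene BST2 from 190 ± 10.4 to 312 ± 27.4 CPM. NF-kB and inflammatory genes were 4 higher and 7 lower of 19 (camera adjusted p = 0.795), and 7 higher and 6 lower with scaling by library totals. The list's median (0.07) differed in sign from its mean (-0.07) and its test, which pointed down. NFKB1 (-1.01) and ICAM1 (-0.96) fell, whereas BIRC3 (1.79) and NFKB2 (0.82) rose.

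Epithelial genes did not pass as a group (6 higher, 3 lower of 19, camera adjusted p = 0.274). The epithelial transcription factor gene ELF3 rose from 8.37 ± 1.47 to 51.4 ± 1.46 CPM, the tight junction genes CLDN7 (5.88-fold) and CLDN4 (3.46-fold) rose, and KRT7 fell from 929 ± 8.11 to 322 ± 14.8 CPM. Mesenchymal genes were 7 higher and 7 lower of 18, with a median log2 fold change of -0.09 that became 0.04 with scaling by library totals (camera adjusted p = 0.482). TAGLN (-1.45), CDH2 (-0.89) and TGFBI (-0.61) fell. SPARC (158 ± 6.02 to 242 ± 21.3 CPM) and the transcription factor gene TWIST1 (5.47 ± 0.821 to 10.4 ± 1.03 CPM), named after their values had been seen, rose. Of 12 gastric and intestinal lineage genes tested, 4 were higher and 2 lower (camera adjusted p = 0.427). MUC1 (17.3 ± 0.937 to 52.7 ± 2.94 CPM), CLDN18 (3.21-fold) and GATA6 (2.01-fold) rose and MUC6 fell (-0.53).

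Markers of cell types foreign to the culture were also examined. Of 15 leukocyte markers, 4 were tested, with 1 higher and 1 lower (camera adjusted p = 0.904), and the list's median (-0.31) differed in sign from its mean (0.34) and its test, which pointed up. CSF1R fell from 4.75 ± 0.559 to 2.97 ± 0.239 CPM (-0.69). Fibroblast and endothelial markers were 5 higher and 3 lower of 10 (camera adjusted p = 0.274). The collagen genes COL1A1 (15.97 ± 0.249 to 35.6 ± 1.79 CPM) and COL3A1 (3.20-fold) and the proteoglycan gene DCN (5.03-fold) rose, and THY1 fell (-0.88).

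**Figure D3:**
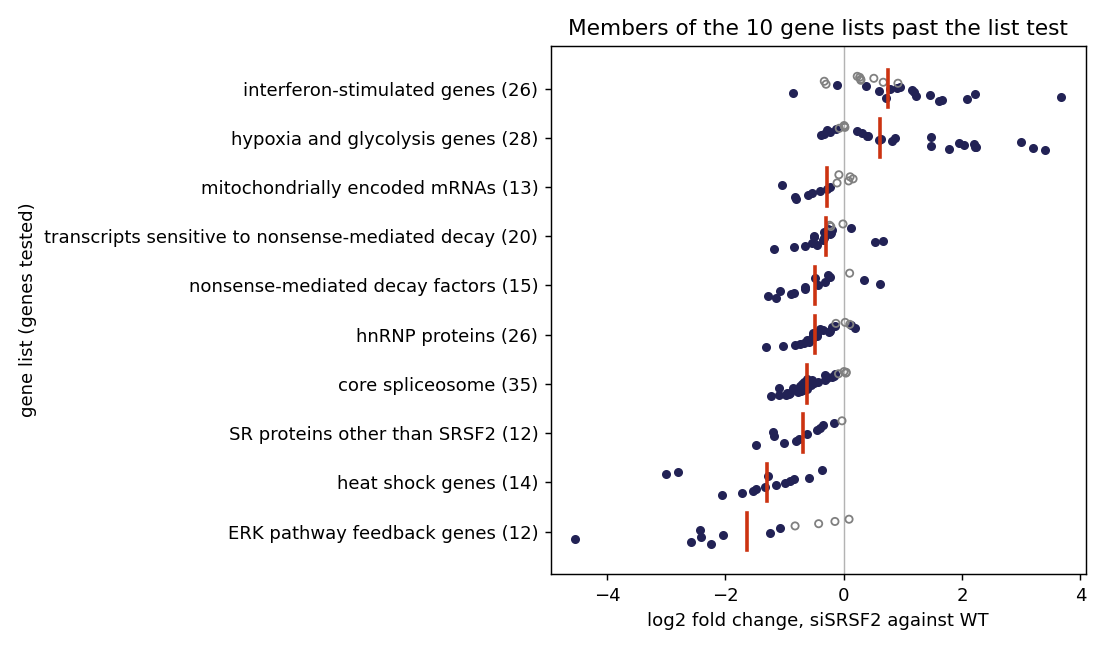
The x axis gives the log2 fold change of siSRSF2 against WT and the y axis the 10 gene lists past the camera test, with the number of tested genes in brackets. Each circle is a gene, filled where it passed an edgeR adjusted p of 0.05 and open where it did not, and red bars mark list medians. The medians run from -1.64 for ERK pathway feedback genes to 0.75 for interferon-stimulated genes.

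Long non-coding RNAs differed from protein-coding genes in the balance of their changes. Of 4570 tested, 1572 (34.4%) rose and 737 (16.1%) fell, with a median log2 fold change of 0.25. Of 14233 protein-coding genes, 4694 (33.0%) rose and 5416 (38.1%) fell, with a median of -0.03. Long non-coding RNAs took 6.46% ± 0.158 of all counts in WT and 10.6% ± 0.383 in siSRSF2 libraries (SD, n = 3 per group). MALAT1, an abundant nuclear transcript of splicing speckles, accounted for 2.96% ± 0.180 and 6.29% ± 0.309 of counts. Its log2 fold change was 0.96 (SE 0.054, edgeR adjusted p = 6.67e-14). NEAT1, the scaffold of nuclear paraspeckles, rose from 852 ± 75.6 to 2927 ± 190 CPM. MALAT1 and NEAT1 were singled out after their values had been seen.

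In total, 10 of the 28 gene lists passed camera with its preset correlation of 0.01, and none passed with an estimated correlation (smallest camera adjusted p = 0.178). The estimated setting also takes its degrees of freedom from the few libraries, so the loss of calls does not measure correlation among members alone. Adjusted over the list alone, the counts of higher and lower members differed from those over all genes in 4 lists. These were 3 higher and 21 lower hnRNP genes, 11 higher and 9 lower homologous recombination genes, 7 higher and 16 lower ribosomal protein genes, and 6 higher and 3 lower fibroblast and endothelial markers. Of the 137 genes named by the fixed rule, 55 share exon positions with another annotated gene, 42 of them with a gene on the opposite strand.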

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

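Thinning and the offsets for GC content and length were chosen after seeing the data. SRSF2 was lower and past the threshold under all 18 alternatives, with log2 fold changes from -1.06 (without siSRSF2 replicate 3, and close to it with no filter beyond a total count above 0) to -0.85 (library totals). The counts of changed genes in each direction stayed within 1.5 times those reported, from 5569 to 8560 higher and from 4941 to 7613 lower. Of the reported calls, 87.1% were kept by DESeq2 (12192 genes), 99.2% by limma voom, 90.2% with library totals and 75.1% in the test against a change of 1.2-fold, and none of these called a gene the other way. In that last test SRSF10 (adjusted p = 0.97), CLK3 (0.0683), RPL6 (0.0813) and RPS15 (0.375) lost their calls. Offsets for GC content and length called 11 genes the other way. DESeq2 gave no adjusted p for 27204 entries, which were left out of its counts. In simulated counts, 2-fold changes were recovered in 27.8% of genes below a mean of 1 CPM and in 90.6% of the others. At 4-fold, 38 of the 46 planted genes had a mean of at least 1 CPM, and the few below it were all recovered (100%). Depth was not varied there. Only 46 to 50 genes were planted per fold, against 59.1% of genes called here, so these shares need not hold for this comparison.

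The counts over 2-fold moved by more than 1.5 times under some settings. With a mean CPM of at least 1, 1991 genes were higher and 881 lower, where fewer genes (17174) were tested. With library totals, 929 were lower, where the median of all genes had shifted by 0.13. SRSF11, which did not pass the test, changed sign in 3 settings, to 0.10 (0.09688) with library totals, 0.02 (0.02056) with a mean CPM of at least 1 and 0.04 (0.04311) without siSRSF2 replicate 3, within a range of -0.11 (-0.1107) to 0.04 when each library was left out. With no filter beyond a total count above 0 it passed as lower (-0.11, edgeR adjusted p = 0.048). Apart from the shift under library totals, the cause was not tested. Of the 28 lists, camera called 10, 0 with an estimated correlation, 9 with library totals and 8 with a mean CPM of at least 1. The directional fry test called 26, but it does not compare a list with other genes. Estimated correlations of the ERK feedback (-0.00716), interferon (0.00687) and decay-sensitive transcript (0.00762) lists lay below the preset 0.01. Their camera p before adjustment still rose, for ERK feedback from 5.05e-05 to 0.0129. Higher correlation among members is therefore argued against as the cause in these lists. It lay above 0.01 in the other called lists. With an estimated correlation, camera also takes its degrees of freedom from the libraries rather than from the genes. That raises p at a given statistic, whatever the correlation. How much each contributed in those other lists was not measured. Other causes were not tested.

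Leaving out each library in turn gave 6596 to 6915 genes higher and 6363 to 6926 lower, 3186 to 3293 higher and 1367 to 1601 lower over 2-fold, SRSF2 at -1.06 to -0.94, and 9 to 10 lists. The list that lost its call was the mitochondrially encoded mRNAs, without siSRSF2 replicate 2 or 3.

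Replicate numbers are shared between the groups. The deviations of same-numbered libraries correlated at 0.013, -0.047 and -0.046 across genes, and not every library correlated best with its own number. No sign of pairing was seen. Deviations from means of 3 libraries cannot exclude it, and the labels do not say whether samples were paired. With the replicate number as a block, 6927 genes were higher and 6770 lower (3135 and 1409 over 2-fold), SRSF2 stood at -0.99, 10 lists passed, and the block changed no call among the genes named.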

Other observations

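All tests of the lists in the next paragraphs were chosen only after the result was seen, as were the count of splits, the look for a batch label, the share without MALAT1 and the comparison of SRSF2 with its family. Thinning, the offsets, the olfactory receptor genes and the overlap with MFSD11 were chosen after the patterns had been seen, with what each would show stated before its result was known. The 5 lists, over which p was adjusted, were written after the largest changes and the fixed lists had been examined, all 5 are reported, and the version without members whose values had been seen was added after the full lists had been tested.

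Genes of ribosome biogenesis, from the synthesis of ribosomal RNA to the assembly of ribosomal subunits, fell without exception among 44 tested. Their median log2 fold change was -1.19 (camera adjusted p = 8.84e-20, and camera adjusted p = 0.00405 with an estimated correlation). RRP9 fell from 113 ± 3.82 to 24.8 ± 1.41 CPM, EBNA1BP2 from 412 ± 11.6 to 134 ± 3.72 CPM, UTP20 from 611 ± 16.6 to 216 ± 3.38 CPM and RRP12 from 235 ± 6.65 to 79.0 ± 2.11 CPM (SD, n = 3 per group). Genes of MYC-linked growth metabolism were lower in 21 of 22 cases (median -0.72, camera adjusted p = 1.88e-08; adjusted p = 0.0295 with an estimated correlation). These included ODC1 (-2.26), the rate-limiting enzyme of polyamine synthesis, and the amino acid transporter genes SLC3A2 (-1.33) and SLC7A5 (-1.26), while SHMT2 rose (0.57). Chaperonin and co-chaperone genes outside the heat shock list were lower in 17 of 20 cases and higher in 1 (median -0.72, camera adjusted p = 4.21e-07; adjusted p = 0.0443 with an estimated correlation), with CHORDC1 (-1.36) and CCT2 (-1.34) among them.

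Genes induced by FOXO factors or starvation rose in 27 of 29 cases and fell in 2, SQSTM1 (-0.17) and SESN1 (-0.18), neither of which passed with library totals (edgeR adjusted p = 0.534 and 0.567) or against a change of 1.2-fold (0.971 and 0.796). The median log2 fold change was 1.60 (camera adjusted p = 7.9e-11; adjusted p = 0.0293 with an estimated correlation). SESN1 also lost its call under 8 other alternatives, among them DESeq2 (adjusted p = 0.0559). KLHL24 (3.91), CCNG2 (4.22), TXNIP (3.44) and the death ligand gene TNFSF10 (3.73) rose. Lysosome and autophagy genes were 19 higher and 6 lower of 32 (camera adjusted p = 0.00356; adjusted p = 0.123 with an estimated correlation), with the autophagy kinase gene ULK1 (1.75) and the cathepsin gene CTSF (1.88) higher and CTSL (-0.48) lower.

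A hypothesis from these groups is lower growth signalling in siSRSF2 libraries, by growth factors or nutrients. It needs lower ribosome biogenesis and MYC-linked lists and a higher FOXO and starvation list. With the members seen first left out, 3 of these 3 lists passed in that direction, but all member values were known by then, so this decides nothing and the hypothesis stays open. Silencing of SRSF2, transfection, cell density and spent medium cannot be told apart as a source of such a difference, because the labels name no control siRNA and no culture batch. Of the full lists, 3 MYC-linked genes and 2 FOXO and starvation genes also stand in the fixed lists.

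The breadth of the difference, 59.1% of tested genes, was weighed against technical explanations. A difference in depth as the whole cause is argued against by thinning, after which 91.52% of the calls were still made in the same direction, and bias of GC content or length by offsets, after which 93.33% were. The real split gave 13991 genes and the highest of the other splits 0, with 1 of the 10 splits reaching the real count, which is too few splits for a share under 0.05. Every other split mixes the 2 groups, so a large group difference enters its spread and lowers its count whatever the cause. The contrast therefore does not weigh between explanations. Separate handling of the cultures or libraries of the 2 groups cannot be told apart from the siRNA, since no batch is labelled and libraries within a group varied little (6.27% biological coefficient of variation). An effect of SRSF2 silencing stays open alongside it.

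The higher share of long non-coding RNA counts rested largely on MALAT1, with a remainder. Without MALAT1 and the entries overlapping it, the share was 3.61% ± 0.0412 in WT and 4.61% ± 0.101 in siSRSF2, a difference of 0.999 percentage points (SD 0.109), so MALAT1 was not the whole of it. Genomic DNA or other background over the genome is argued against by olfactory receptor genes, whose count density did not rise (0.0545 to 0.0510 CPM per kb), a ratio of -0.00835 to the rise over long non-coding RNA genes other than MALAT1. Differences in nuclear RNA yield between the groups and an effect of SRSF2 silencing were not tested and stay open.

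The fall of SRSF2 was weighed against a fall of SR protein genes in general. SRSF2 lay below the mean of the other SR protein genes (difference -0.281), but within the spread of log2 fold changes among them (SD 0.445). SRSF6, SRSF8, SRSF3 and, by less than its SE, SRSF7 had lower values. A general fall with no further fall of SRSF2 therefore stays open. Reads shared with an overlapping gene as the whole cause are argued against by MFSD11, whose log2 fold change was -0.407 against -0.98 for SRSF2. How much of the fall came from the siRNA and how much from what lowered the other SR protein genes remains open, since no sample separates them.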
